A study of Mus musculus with 4 samples.

How the data were processed

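RNA was measured in mammospheres, the floating colonies that mammary cells form when they cannot attach, grown for 7 days from basal mammary cells of Balb/C mice aged 4 months. Per the labels' protocols, the basal cells were isolated by fluorescence-activated sorting. The mice had received bisphenol A (BPA, a plastics monomer with estrogenic activity) at 25 µg/kg/day by gavage for 3 weeks from day 21, or sesame oil. Part of each arm then received 7,12-dimethylbenz[a]anthracene (DMBA, a chemical carcinogen) as a single 30 mg/kg gavage at 2 months. Total RNA was extracted with the miRNeasy kit and libraries were made with the Illumina TruSeq RNA protocol, per the labels' protocols. Each of the 4 groups (control, BPA, DMBA, BPA+DMBA) is 1 library, made from pooled spheres of 5 animals.

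The authors deposited raw read counts per gene symbol for 22609 genes in each library, together with 5 summary entries for reads given to no gene. The submitters' processing notes name CASAVA 1.8.2, HTSeq, DESeq and the mouse build mm9. What each tool was used for, the aligner and the strand setting are not given in the sources used here. The deposited values are whole numbers and were used without change. Counts summed over genes came to 30627055 in control, 19672730 in BPA, 26682738 in DMBA and 15672532 in BPA+DMBA. The summary entries were left out of library sizes and tests. Of all deposited counts, reads outside annotated genes made up 13.5% in control, 13.0% in BPA, 11.9% in DMBA and 11.3% in BPA+DMBA. Reads aligned to more than 1 place made up 22.9%, 23.3%, 25.6% and 25.3% in the same order, and reads on overlapping genes 0.435%, 0.441%, 0.443% and 0.449%. The entries for unaligned reads and for low alignment quality were 0 in every library. A gene counted 0 times can still hold up to 3 counts, which is 0.098 CPM (counts scaled to library size) in control, 0.153 in BPA, 0.112 in DMBA and 0.191 in BPA+DMBA. These floors use the summed counts above, while all other CPM values and fold bounds use the library sizes scaled as described below. No pair of libraries held the same counts: chi-square per degree of freedom between libraries ran from 12.1 to 71.7.

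The 13638 genes with at least 20 counts in at least 1 library were kept. Counts were scaled by the trimmed mean of M-values (TMM) in edgeR, with factors of 0.969 for control, 0.973 for BPA, 1.05 for DMBA and 1.01 for BPA+DMBA. For each single pair of libraries the log2 ratio of CPM was taken with a prior count of 2, beside an exact 95% Clopper-Pearson interval of the count ratio. Such intervals and the count floors cover counting error only. A gene was counted as differing when the ratio was at least 2-fold and the interval excluded equality, and no p-value was computed for a single pair, which compares 2 libraries and not 2 conditions. The 2 by 2 layout was also fitted with an additive model of BPA and DMBA by edgeR's quasi-likelihood test on all 4 libraries, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. That model keeps 1 residual degree of freedom, the interaction, which takes the place of replicates. Where BPA and DMBA interact, that spread is too large and the test too strict for those genes. Departure from additivity was the difference between the BPA log2 ratios with and without DMBA, with a counting interval from the 4 libraries.

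Gene lists for cell types, pathways and RNA quality, the groups, the tests and the rule for naming genes were fixed before the data were examined. Of those lists, 36 had at least 1 kept gene, and mitochondrially encoded transcripts had 0. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on expression in 20 bins, and a list below percentile 2.5 or above 97.5 was said to stand apart. List genes are regulated together, so these percentiles describe the libraries and overstate how unusual a list is. For each factor the rule named up to 10 higher and 10 lower genes that differed at least 2-fold the same way in both pairs, ranked by the smaller ratio. For each single pair it named the 8 higher and 8 lower genes ranked by the interval bound nearest equality, and for departure from additivity the 5 highest and 5 lowest. Predicted, clone-named and small RNA genes were left out of the rule. For each list it took up to 4 members with the largest ratios, and Esr1, Pgr, Cyp1a1, Cyp1b1, Ahr, Krt5, Krt14, Trp63, Krt8 and Krt18 were given whatever their values. Genes outside the rule are identified where they appear.

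The additive test and its DESeq2 and likelihood ratio alternatives, the rules for single pairs and for departure, the list percentiles and the removal of the length trend from pair ratios were tested on simulated data. The fits with a single term, with libraries left out or with length offsets were not. With 200 of 13638 genes changed in each of 5 simulations at the gene-wise dispersions of these libraries, the additive test recovered 59.5%, 88.8%, 97.6% and 100% of genes changed 1.5, 2, 4 and 8-fold for BPA, and 58.5%, 83.4%, 97.6% and 100% for DMBA. Of the simulated calls, 13.9% for BPA and 12.4% for DMBA were false, above the nominal 5%, against 3.67% and 4.02% when all genes shared 1 dispersion. The rule for single pairs was run on simulated BPA and control libraries of 13638 genes with a shared dispersion. It took in 7.6%, 46.4%, 97.2% and 99.2% of genes changed 1.5, 2, 4 and 8-fold and 0.25% of unchanged genes. That share was not computed for BPA at gene-wise dispersions, so 0.25% may be too low. At gene-wise dispersions the rule took in 0.54% of unchanged genes in DMBA against control with the length trend removed. Of 720 simulated unchanged lists, 51 (7.08%) stood apart, in single pairs against control and with genes drawn independently. At gene-wise dispersions, the departure rule took in 10.4%, 47.6%, 98.0% and 98.4% of genes changed 1.5, 2, 4 and 8-fold in BPA+DMBA and 1.91% of unchanged genes. DESeq2 recovered 35.3%, 73.1%, 89.6% and 96.4% of such genes for DMBA with 3.04% of calls false, and the likelihood ratio test 61.0%, 90.4%, 98.4% and 100% with 15.5% false. For BPA 2.77% and 15.4% of their calls were false. A length trend put into simulated DMBA libraries gave a Spearman correlation of -0.383 in DMBA against control, and 0.0019 after its removal, with 42.4% of genes changed 2-fold and 99.6% of those changed 4-fold taken in.

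Transcript length and GC content came from GENCODE release M21, by symbol for 20284 genes and by older symbol for 1926, with 399 not matched. Among kept genes 99.06% had a value. That annotation uses another build than the files, so no coordinates are given. Alternatives were DESeq2's Wald test, edgeR's likelihood ratio test, DESeq2 size factors, total counts, a minimum of 100 counts, no low-count filter, prior counts of 0.5 and 5, a 4-fold threshold, each factor alone, and libraries thinned to the smallest total. Removal of the trend with transcript length and leaving out each library in turn were added after seeing the data. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.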

Results

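Gene expression was profiled by RNA sequencing in mammospheres grown from sorted basal mammary cells of mice exposed to BPA around puberty, to DMBA at 2 months, to both or to neither. The 4 groups held 1 library each, from spheres of 5 pooled animals, so there were no replicates: p-values rest on the spread across the 2 by 2 layout, and intervals cover counting error only. Counts assigned to genes totalled 30627055 in control, 19672730 in BPA, 26682738 in DMBA and 15672532 in BPA+DMBA. Across 13638 genes, the correlation of log2 CPM between libraries was highest for control and BPA (r = 0.994) and for DMBA and BPA+DMBA (r = 0.992), and lowest for control and DMBA (r = 0.975). These correlations are across genes, which are not independent replicates.

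The effect of DMBA was read from 2 pairs that share no library, DMBA against control and BPA+DMBA against BPA. Genes of basal and squamous epithelium rose in both. Krt5, a keratin of basal cells, rose by a log2 change of 1.95 in the additive fit (SE 0.145, edgeR adjusted p = 0.00274), Krt14, its partner keratin, by 1.46 (SE 0.0983, adjusted p = 0.00241), and Trp63, a transcription factor of basal epithelium, by 0.97 (SE 0.146, adjusted p = 0.0118). Krt6a, a keratin of stressed and stratified epithelium, rose by 2.69 (SE 0.124, adjusted p = 0.00209). Krt8 and Krt18, keratins of luminal cells, had log2 values of -0.01 (SE 0.104, adjusted p = 0.942) and -0.31 (SE 0.103, adjusted p = 0.0965).

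Among 19 measured genes of keratinocyte and squamous differentiation, 15 rose, 0 fell and the others did not pass the test. The median log2 change over both pairs was 1.94, and 17 rose when adjusted over the list alone. Krt16 was 2.94 higher in DMBA against control and 2.37 higher in BPA+DMBA against BPA on the log2 scale, Sprr1a, an envelope protein of cornified cells, 3.35 and 1.76, and Cnfn, another envelope protein, 3.10 and 2.56. Dsg1b, a desmosomal cadherin, was 3.20 and 3.37 higher. Among 20 basal and myoepithelial markers, 11 rose and 0 fell (13 adjusted over the list alone), with a median of 0.82. Smooth muscle genes led them, and which cells expressed these was not tested. Myh11, a smooth muscle myosin, rose by 2.66 (SE 0.163, edgeR adjusted p = 0.00209), and Actg2, a smooth muscle actin, by 3.41 (SE 0.337, adjusted p = 0.00462). Krt6a and Krt6b, Sprr1a and Sprr1b, and Gsta1 and Gsta2 are close paralogs whose reads may be split or lost in counting.

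Cell cycle genes rose as a group. Of 35 measured members 33 rose and 0 fell (34 adjusted over the list alone), with a median of 0.66, and DESeq2 called 17. Rrm2, a ribonucleotide reductase subunit, was 0.99 and 0.78 higher in the 2 pairs, Plk1, a mitotic kinase, 1.02 and 0.69, and Ccnb1, a mitotic cyclin, 0.96 and 0.75. Of 28 p53 target and DNA damage response genes 4 rose and 0 fell (5 and 2 adjusted over the list alone), with a median of 0.04, percentile 88.5. Cdkn1a, a cell cycle inhibitor induced by p53, was 0.77 and 0.45 higher.

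Among 14 genes of the aryl hydrocarbon receptor, which binds DMBA, and of DMBA metabolism, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.22, percentile 99.04. Cyp1a1, an oxidase induced by that receptor, rose by 1.39 (SE 0.257, adjusted p = 0.0206), while Cyp1b1 had a log2 value of 0.30 (SE 0.0906, adjusted p = 0.0758) and Ahr itself -0.07 (SE 0.115, adjusted p = 0.730). Aldh3a1, an aldehyde dehydrogenase, was 1.95 and 1.79 higher in the 2 pairs. Gsta2, a glutathione transferase, had 0, 3, 16 and 23 counts in control, BPA, DMBA and BPA+DMBA, which makes it at least 5.68-fold higher in DMBA than in control and 9.24-fold higher in BPA+DMBA than in BPA (95% interval 2.79 to 48.1). Of 26 antioxidant and glutathione genes under NRF2 9 rose and 0 fell (14 and 1 adjusted over the list alone), with a median of 0.27. Setting genes with 0 counts at their bound left the medians of the receptor list (0.25) and this list (0.31) in DMBA against control as they were.

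Luminal progenitor markers had a lower median in both pairs, though single members went both ways. Of 13 measured, 2 rose and 6 fell (3 and 8 adjusted over the list alone). The median was -0.42, percentile 0.01 (-0.47 and -0.46 in the 2 pairs). The mean was 0.08, of the other sign (0.38 and -0.22 in the 2 pairs). Their summed CPM was 19498 in control, 18164 in BPA, 12628 in DMBA and 12749 in BPA+DMBA. Trf, the iron carrier transferrin, was lower by log2 values of -1.48 and -0.78, and Aldh1a3, a retinaldehyde dehydrogenase, was higher by 1.26 and 1.14. Csn2, the milk protein beta-casein, had 2, 0, 162 and 3 counts in control, BPA, DMBA and BPA+DMBA, so its level in the DMBA library was 86.2-fold that in control (95% interval 23.5 to 718) and was not shared by BPA+DMBA. It was nevertheless among the 2 markers counted as rising (log2 6.28, SE 0.575, edgeR adjusted p = 0.00410), although only the DMBA library was high. Among 11 hormone-sensing luminal markers 4 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.49: Pgr, the progesterone receptor, rose by 1.15 (SE 0.229, adjusted p = 0.0251), and Prlr, the prolactin receptor, was lower by -0.89 and -0.96. Esr1, the estrogen receptor, had a value of -0.44 (SE 0.259, adjusted p = 0.298). Of 14 keratin and junction markers shared by luminal cells 0 rose and 1 fell, Muc1, with a median of -0.13 (1 adjusted over the list alone).

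Among 22 regulators of mammary stem and basal progenitor cells 7 rose and 2 fell (7 and 6 adjusted over the list alone), with a median of 0.15, percentile 98.9. Id4, a regulator of basal cells, was 1.36 and 0.93 higher in the 2 pairs, and Bcl11b, a transcription factor, 1.19 and 1.00. Markers of other cell types moved in these libraries too. Of 12 endothelial and pericyte markers 6 rose and 0 fell (7 adjusted over the list alone), with a median of 0.82, led by Esam at 2.23 and 2.84. Esam had 25, 9, 119 and 62 counts in control, BPA, DMBA and BPA+DMBA. The summed CPM of these markers was 423, 422, 418 and 519 in the same order, so the sum did not rise in DMBA against control. Of 15 fibroblast markers 3 rose and 0 fell (4 adjusted over the list alone), with a median of -0.00 (-0.34 and 0.52 in the 2 pairs) and a mean of 0.18. Of 4 immune markers 2 rose (2 adjusted over the list alone), with a median of 0.30, and of 3 adipocyte markers 1 rose (1 adjusted over the list alone), with a median of 0.69. Alas2, the 1 measured red blood cell marker, had 17, 8, 23 and 14 counts and no call.

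The genes that fell most were a mixed set. By the naming rule they included Kcnma1, a potassium channel (-3.43 and -3.02), Adra1a, an adrenergic receptor (-3.35 and -2.48), Mmp12, a metalloelastase (-1.76 and -2.31), and Slc1a2, a glutamate transporter (-1.67 and -1.80). Igfbp5, a binding protein of insulin-like growth factors, fell by 1.99 (SE 0.322, adjusted p = 0.0140), Fcgbp, a mucus component, by 2.13 (SE 0.222, adjusted p = 0.00530), and Pigr, the polymeric immunoglobulin receptor, by 1.64 (SE 0.093, adjusted p = 0.00209).

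**Figure D1:**
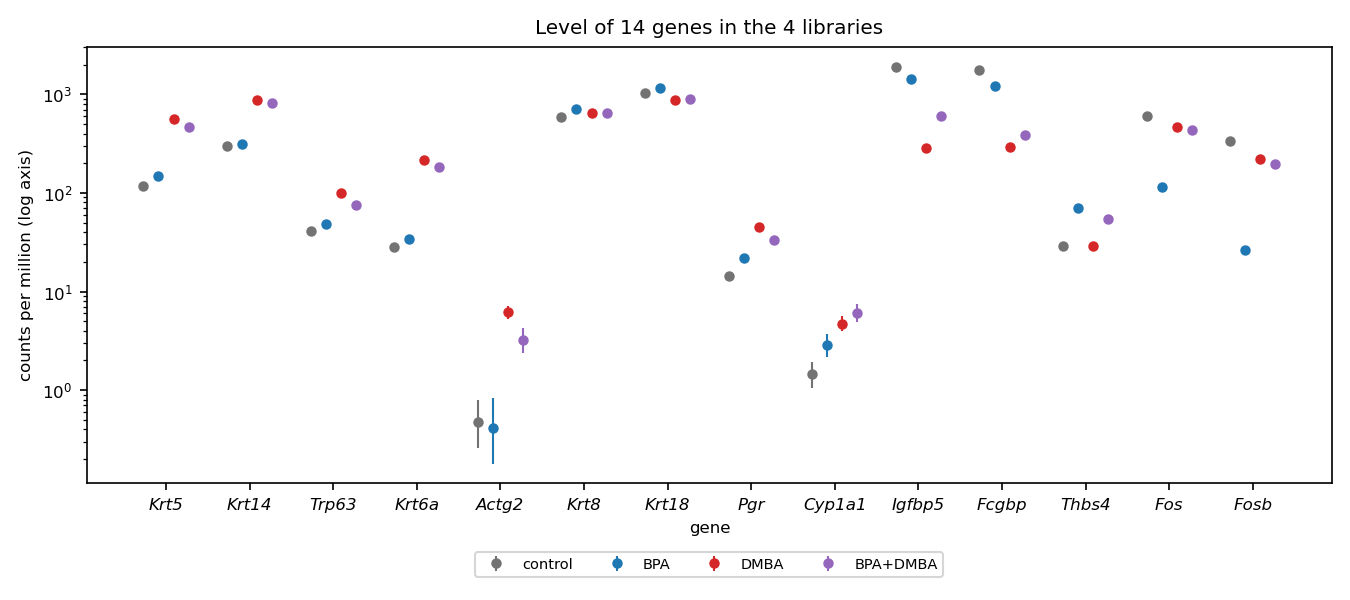
Level of 14 genes in CPM (log axis) in the 4 libraries, with bars for exact 95% Poisson intervals (counting error only, 1 library per group). Krt5 stood at 118 in control and 149 in BPA against 559 in DMBA and 468 in BPA+DMBA, while Fosb was low in the BPA library alone among the 4.

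In the additive fit 1962 genes passed for DMBA, 909 higher and 1053 lower, with a median absolute log2 change of 0.57, and 442 of them changed at least 2-fold (324 higher, 118 lower). DESeq2 called 675 (341 higher, 334 lower), and thinning all libraries to the smallest total left 781. With DMBA as the only term edgeR called 2610 in all 4 libraries and 1049 without the control library, where the lone unexposed library is assumed to vary like the others. With total counts alone as scaling the split was 889 higher and 431 lower. Log2 ratios also followed transcript length, with a Spearman correlation across genes of -0.285 in DMBA against control and -0.335 in BPA+DMBA against BPA. With that trend removed 923 genes passed, 537 higher and 386 lower, and of the list members 14 squamous, 12 basal, 28 cell cycle and 0 ribosomal genes passed.

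Without a test, 893 genes differed at least 2-fold in DMBA against control (578 higher, 315 lower) and 510 in BPA+DMBA against BPA (378 higher, 132 lower). Total counts alone gave 707 higher and 230 lower in the former. Both pairs shared 300 genes moving the same way, 223 higher and 77 lower, where independent lists of these sizes would share 16.0 and 3.05, and 3 moved opposite ways. The correlation of the ratios across genes was r = 0.638 (Spearman 0.580). Krtdap, a keratinocyte protein, was 4.44 higher in DMBA against control and 2.28 higher in BPA+DMBA against BPA.

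**Figure D2:**
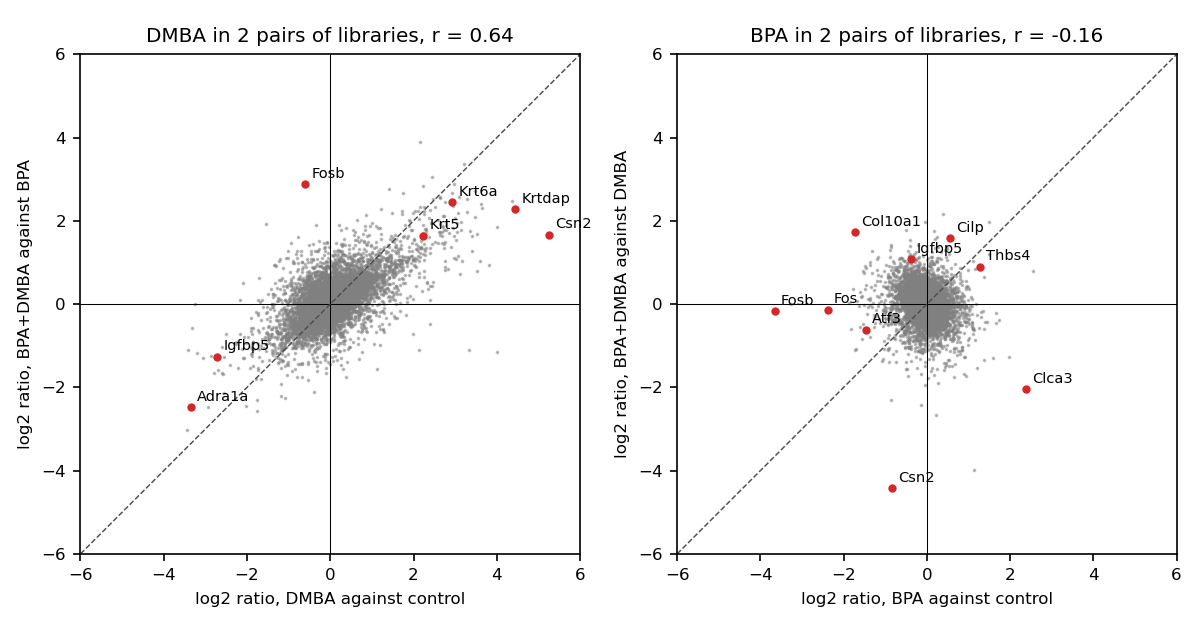
Log2 ratio of each of 13638 genes in the 2 pairs that share no library, for DMBA (left) and BPA (right), with named genes in red and the line of equality dashed. The ratios went together for DMBA (r = 0.638) and slightly against each other for BPA (r = -0.158).

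The study's title places pubertal BPA exposure and mammary stem cells at its centre. Most genes were alike in BPA and control: 95.46% differed by less than 1.5-fold. Immediate early genes, which respond within minutes to signals and stress, were lower in the BPA library. Fosb had 9854 counts in control and 503 in BPA, a log2 ratio of -3.66, Fos 17718 and 2196, a ratio of -2.38, and Atf3, a stress-induced factor, 1273 and 295, a ratio of -1.47. The median of the 19 measured was -0.40, and 5 were at least 2-fold lower. Mmp13, a collagenase, was at -1.50, and Thbs4, a matrix glycoprotein, was higher at 1.28 (95% interval 1.16 to 1.41).

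Stem and basal progenitor regulators had a median of 0.11 in BPA against control, percentile 99.6, with 0 of 22 at least 2-fold apart. They had 0.02 in BPA+DMBA against DMBA, percentile 63.4, and 0.04 over both pairs, percentile 90.0. In BPA against control basal markers had a median of 0.04, percentile 78.1. Fibroblast markers were lower, with a median of -0.34, led by Thy1 at -0.68 and Col3a1, a fibrillar collagen, at -0.60. Endothelial and pericyte markers had a higher median (0.55), although their summed CPM was 423 in control and 422 in BPA. Medians were also higher for cholesterol and fatty acid synthesis (0.22), cell cycle genes (0.16) and interferon response genes (0.14). Summed CPM of the cholesterol and fatty acid genes was nevertheless lower, at 8378 in control and 7601 in BPA. For cell cycle genes it was 1103 and 1217, and for interferon response genes 1345 and 1415. In all, 113 genes differed at least 2-fold, 37 higher and 76 lower. The rule took in 0.25% of unchanged genes in simulation, but at a shared dispersion only. Of the 36 lists 21 stood apart, against a nominal 1.8 for independent genes. Of simulated unchanged lists 7.08% did so, but genes were drawn independently there, while list genes are regulated together.

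BPA+DMBA against DMBA gave the same comparison on the DMBA background. Interferon response genes were higher in the combined library, with a median of 0.33, and 5 of 34 were at least 2-fold higher, among them Ifit3 (1.55), Cxcl10 (1.37) and Mx2 (1.30), which had 39 counts or fewer in every library. Fibroblast markers were higher here, with a median of 0.50, led by Col1a1 at 0.86, as were matrix and basement membrane genes (0.37). Basal markers (-0.29) and squamous genes (-0.29) were lower, and immediate early genes had a median of -0.07, percentile 2.02, which stood apart below, with Atf3 at -0.61 (95% interval -0.76 to -0.47). Cilp, a matrix protein of cartilage, was 1.59 higher and Igfbp5 1.07 higher, while Atp12a, a proton pump, was lower at -1.90. Csn2 was 30.8-fold lower than in DMBA (95% interval 10.3 to 151), and Csn1s2a, another casein, had 36 counts in DMBA and 0 in BPA+DMBA, at least 6.84-fold lower. In all 148 genes differed at least 2-fold, 58 higher and 90 lower, and 94.1% differed by less than 1.5-fold. How many unchanged genes the rule takes in was not simulated for this pair.

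Over both backgrounds edgeR called 0 genes for BPA. The interaction is the error of this test, so it is too strict for genes that BPA moved differently with and without DMBA. Its recovery was simulated for additive changes only. The smallest adjusted p was 0.517, at Thbs4 (log2 1.09, SE 0.111), and 304 genes had an unadjusted p under 0.05. DESeq2 called 1, Thbs4, edgeR's likelihood ratio test 6, and the fit without a low-count filter 2. Adjusted over the list alone, 3 immediate early genes fell, Atf3, Btg2 and Klf4, as did 2 luminal progenitor markers, Csn2 and Csn1s1, and 1 gene of the unfolded protein and amino acid response, again Atf3, against 0 over all genes. Btg2 and Klf4 were named after their values were seen. The pairs shared 4 genes moving the same way, Myh8 higher and Klk5, Hist2h2bb and Ccdc158 lower, each with 67 counts or fewer in every library, where independent lists would share 0.157 and 0.502 and unchanged libraries simulated at gene-wise dispersions shared 1.1 and 1.49. There were 8 moving opposite ways, and the ratios correlated at r = -0.158 across genes (Spearman -0.135), and r was -0.0548 without a low-count filter, with 47.37% of genes on the same side of 0 in both pairs. The median BPA change over both pairs was -0.29 for immediate early genes, 0.22 for interferon response, 0.13 for cholesterol and fatty acid synthesis, 0.10 for Wnt and 0.11 for Notch pathway genes. It was also 0.22 for endothelial and pericyte markers, 0.13 for TGF-beta and YAP responsive genes and -0.29 for replication-dependent histones. Extracellular matrix had 0.08, epithelial to mesenchymal transition and NF-kB and inflammatory cytokines each 0.06, and basal and luminal progenitor markers each -0.06. Some of these averages joined pairs that did not go together. In BPA against control and BPA+DMBA against DMBA, extracellular matrix had -0.16 and 0.37 and basal markers 0.04 and -0.29. Luminal progenitor markers had -0.13 and 0.0035, and endothelial and pericyte markers 0.55 and 0.0043. The other lists named here had the same sign in both pairs. Of 36 lists, the 13 named here stood apart over both pairs, against a nominal 1.8 for independent genes. The 7.08% of simulated unchanged lists came from single pairs with genes drawn independently. It is therefore no chance rate for this average or for genes regulated together.

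**Figure D3:**
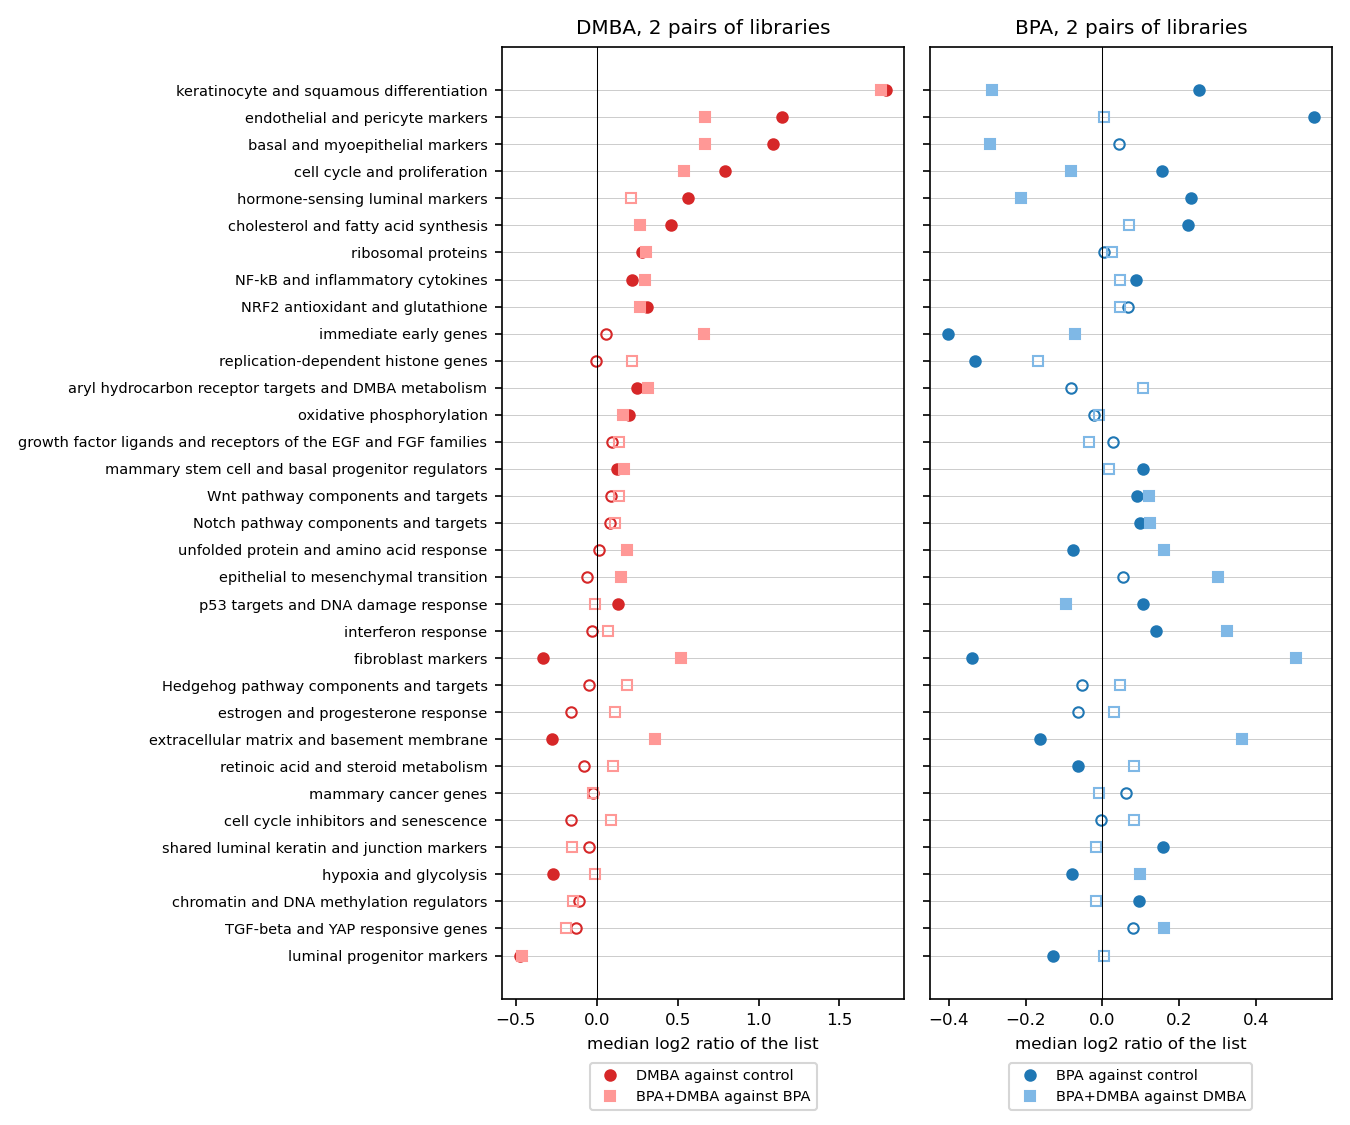
Median log2 ratio of each gene list with at least 5 measured genes, in the 2 pairs for DMBA (left) and BPA (right), with filled symbols where the median stood apart from matched random lists. Squamous genes were highest for DMBA in both pairs (1.79 and 1.76), and fibroblast markers lay on opposite sides of 0 for BPA (-0.34 and 0.50).

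The combined exposure was also set against control. Squamous genes had a median of 1.91, endothelial and pericyte markers 1.06, basal markers 0.75 and cell cycle genes 0.72, while luminal progenitor markers had -0.62. Mt3, a metal-binding protein, was 3.25 higher, Nmu, a neuropeptide, 2.82 and Selp, an adhesion receptor, 2.78, while Abca1, a cholesterol exporter, was lower at -2.11 and Clic6, a chloride channel protein, at -1.93. In all 598 genes differed at least 2-fold, 406 higher and 192 lower.

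Departure from additivity asks whether BPA moved a gene differently with and without DMBA. Fosb departed by 3.48 on the log2 scale (counting interval 3.34 to 3.63), Fos by 2.25 (2.17 to 2.32), Mmp13 by 2.26 (2.03 to 2.49) and Lamc3, a laminin chain, by 2.60 (2.02 to 3.18). Nefl, a neurofilament protein, departed by -2.67 (-3.61 to -1.73) and Tprg by -2.88 (-4.30 to -1.46). In all 417 genes departed at least 2-fold, 245 upward and 172 downward, while the same rule took in 256 unchanged genes per simulation at gene-wise dispersions, which are themselves estimated from these departures. With BPA and DMBA both in the model no residual degree of freedom is left to test it. With the departure as the only term, which puts both exposures into the error, edgeR called 0 genes, and 179 had an unadjusted p under 0.05.

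BPA and DMBA were both compared with the same control library, and 38 genes differed at least 2-fold the same way in both, 21 higher and 17 lower, with 4 opposite. Independent lists would share 1.57 and 1.76, and unchanged libraries simulated at gene-wise dispersions shared 9.3 and 5.07. The correlation across genes was r = 0.407, against a simulated 0.474 with no effect, and the covariance 0.0587 against 0.0348. The control cannot be split, so part of the overlap may come from that library.

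For the remaining lists, the DMBA counts over both pairs are given as genes that rose and fell. Cholesterol and fatty acid synthesis had 12 and 2 of 25 (15 and 3 adjusted over the list alone), with a median of 0.35, although Scd1, an abundant desaturase, was lower by -1.58 and -0.79. Ribosomal proteins had 10 and 0 of 32 (21 and 0 adjusted over the list alone), with a median of 0.29, or 0 passing and a median of 0.13 with the length trend removed. Their counts are uncertain if processed pseudogenes share reads, which was not tested. Oxidative phosphorylation had 0 and 0 of 21, with a median of 0.18, or 0.057 with that trend removed. NF-kB and inflammatory cytokines had 8 and 1 of 26 (9 and 2 adjusted over the list alone), led by Tslp at 0.85 and 2.13. Immediate early genes had 4 and 0 of 19 (4 and 0 adjusted over the list alone) and a median of 0.26, from 0.05 in DMBA against control, percentile 94.7, and 0.66 in BPA+DMBA against BPA, where the BPA library was low. Wnt pathway genes had 7 and 2 of 26 (9 and 5 adjusted over the list alone), led by Wnt10a at 2.00 and 1.07. EGF and FGF family genes had 6 and 2 of 22 (6 and 2 adjusted over the list alone), led by Fgfr3 at 1.58 and 1.23. Notch pathway genes had 4 and 2 of 16 (4 and 5 adjusted over the list alone) and Hedgehog genes 1 and 2 of 11 (1 and 2 adjusted over the list alone).

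Chromatin and DNA methylation regulators had 0 and 5 of 20 (0 and 8 adjusted over the list alone), with Tet2, a methylcytosine oxidase, at -0.54 and -0.52. Hypoxia and glycolysis had 0 and 6 of 26 (0 and 6 adjusted over the list alone), led by Pfkfb3 at -0.83 and -0.63. TGF-beta and YAP responsive genes had 0 and 3 of 16 (0 and 4 adjusted over the list alone), with a median of -0.20. Mammary cancer genes had 2 and 5 of 24 (2 and 6 adjusted over the list alone), with Rb1, a tumour suppressor, at -1.22 and -0.69. Retinoic acid and steroid metabolism had 5 and 5 of 21 (6 and 6 adjusted over the list alone), a median of -0.04 and a mean of 0.16. Estrogen and progesterone response had 4 and 3 of 19 (6 and 4 adjusted over the list alone), a median of -0.04 and a mean of 0.11. Cell cycle inhibitors and senescence had 2 and 1 of 13 (3 and 2 adjusted over the list alone), a median of -0.07 and a mean of 0.04. Epithelial to mesenchymal transition had 3 and 1 of 22 (3 and 2 adjusted over the list alone), and extracellular matrix 2 and 0 of 25 (3 and 1 adjusted over the list alone), a median of -0.04 and a mean of 0.05. Interferon response had 1 and 0 of 34 (0 and 0 adjusted over the list alone). The unfolded protein response (21 genes) and replication-dependent histones (5 genes) had 0 and 0.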

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

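The tests of length or depth as the whole cause against random lists, of the luminal-like share, of the rise of epidermal transcripts, of variation between pools, of genes chosen by the size of the DMBA change, of carried-in epidermis, of BPA exposure whatever the DMBA treatment and of the handling of the BPA pool were chosen after the results they address were seen.

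Squamous and basal genes were higher in both DMBA libraries. A lower share of luminal-like cells would raise the markers of other cell types alike, but the squamous median over both pairs lay 1.94 above the fibroblast median (bootstrap interval over genes 0.95 to 2.39). The basal median lay 0.82 above it, with an interval of 0.08 to 1.52 that crosses the bound of 0.5. Endothelial and pericyte markers had the same median of 0.82 with 6 of 12 passing, adipocyte markers 0.69 with 1 of 3, and fibroblast markers -0.34 and 0.52 in the 2 pairs. Medians of luminal markers did not fall together: they were 0.49 for hormone-sensing, -0.13 for shared luminal and -0.42 for luminal progenitor markers. Krt8 was at -0.01. Summed CPM of luminal progenitor markers was lower in both pairs, at 19498, 18164, 12628 and 12749 in control, BPA, DMBA and BPA+DMBA. In the same order it was 8010, 8757, 7528 and 7428 for shared luminal and 491, 548, 527 and 455 for hormone-sensing markers. The cells had been sorted as basal, but the luminal-like share of the spheres is not known, so for basal genes a lower luminal-like share and a change in basal cells cannot be told apart. Carried-in differentiated epidermis would bring Krt1, Krt10 and Lor. They reached 0.354% of Krt5 plus Krt14 in BPA+DMBA and 0.325% in DMBA, against 0.727% in control and 0.663% in BPA. Krt10 rose from 2.63 to 3.52 CPM and Lor from 0.371 to 1.04 in DMBA against control. The rise of the 3 together was at most 0.178% of the rise of Krt5 plus Krt14 in either pair (counting interval 0.106% to 0.342%). That is under the 10% set for such cells, but Krt5 and Krt14 belong to the basal pattern itself. So these shares cannot exclude a small carried-in part, and undifferentiated epidermal cells were not tested. With the length trend removed the squamous median was 1.87, above the bound of 1 set beforehand, although its interval of 0.99 to 2.35 just crosses it. The squamous median still lay 1.70 above the upper limit of matched random lists (0.82 to 2.17) and the basal median 0.73 above it (0.11 to 1.27), which argues against the trend as the whole cause. For squamous genes the smaller median in the DMBA pairs exceeded the larger between pools of like DMBA treatment by 1.47 (0.65 to 1.61). For basal genes this was 0.37 (-0.08 to 0.81), which crosses 0. These bootstrap intervals measure spread over genes and not between pools, and pools of like DMBA treatment gave only 2 differences. So variation between pools and DMBA cannot be told apart, although for squamous genes that variation would have to exceed those 2 differences. A larger difference shared by both DMBA pools, a direct effect of DMBA and a change in which cells form spheres remain open and were not tested.

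Immediate early genes were lower in the BPA library. BPA exposure acting alike on both DMBA backgrounds would lower them in BPA+DMBA against DMBA too. That median was -0.07 (interval -0.13 to 0.00), above the bound of -0.20. The interval measures spread over genes and not between pools, and each group is 1 pool, so this cannot decide the question. A lowering shared by both backgrounds stays open. That median also stood apart (percentile 2.02), and Atf3 was at -1.47 and -0.61. With all libraries thinned to the same total the median in BPA against control was -0.37, below the bound of -0.20 set beforehand, although its interval of -0.89 to -0.18 just crosses it. It still lay at -0.32 from the lower limit of matched random lists (-0.84 to -0.13), which argues against lower depth as the whole cause. The BPA group is 1 pool, so handling of that pool and its group cannot be told apart. A BPA effect confined to animals without DMBA also stays open.

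The BPA ratios tended slightly in opposite directions on the 2 backgrounds, with r = -0.158 across genes, 47.37% of genes on the same side of 0, and r = -0.0548 without a low-count filter. Trends with length and GC content do not account for it, since r was -0.167 with both removed (interval -0.201 to -0.138). Over the 11676 genes not called for DMBA r was -0.160 (interval -0.192 to -0.129), but this decides nothing, since the error of the additive fit is the difference between the BPA ratios and keeps genes with opposite ratios uncalled. Over the 6819 genes under the median absolute DMBA change r was -0.0889 (-0.131 to -0.0443), which crosses the bounds of -0.1 and -0.05, so genes moved by DMBA and other causes cannot be told apart. Counting error alone gave simulated values from -0.0403 to 0.0481. Variation between pools and an interaction of BPA with DMBA remain, and 1 library per group cannot separate them.

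Some genes drew attention because they differed at least 2-fold in opposite directions under the same exposure on the 2 backgrounds, and these differences were not tested. For BPA, the log2 ratios against control and on the DMBA background were -1.17 and 1.12 for 6430550D23Rik, 2.39 and -2.04 for Clca3, -1.73 and 1.74 for Col10a1, and 1.20 and -1.54 for Cpa4. They were 1.37 and -1.34 for Cyyr1, -1.33 and 1.27 for Lamc3, 1.59 and -1.29 for Tprg, and 1.97 and -1.27 for Zan. Clca3 had 0, 7, 22 and 2 counts in control, BPA, DMBA and BPA+DMBA, so its level in BPA was at least 3.62-fold that in control. For DMBA, the ratios without and with BPA were -1.54 and 1.93 for Col10a1, -1.21 and 1.07 for I830012O16Rik, and 1.12 and -1.55 for Nefl. Several of these genes were chosen after their values were seen, by this difference in direction and not by the naming rule.

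Gene lists that stood apart in opposite directions on the 2 backgrounds were noted in the same way, also without a test of the difference. For BPA the medians against control and on the DMBA background were 0.23 and -0.21 for hormone-sensing luminal markers, -0.34 and 0.50 for fibroblast markers, 0.25 and -0.29 for squamous genes, and 0.11 and -0.095 for p53 targets. They were 0.16 and -0.081 for cell cycle, -0.16 and 0.37 for extracellular matrix, -0.080 and 0.10 for hypoxia and glycolysis, and -0.076 and 0.16 for the unfolded protein response. For DMBA the medians without and with BPA were -0.34 and 0.52 for fibroblast markers and -0.28 and 0.36 for extracellular matrix.

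Of the reads given to no gene, 2 kinds were a larger share in the 3 exposed libraries than in control, a difference that was not tested. Reads aligned to more than 1 place made up 23.3% in BPA, 25.6% in DMBA and 25.3% in BPA+DMBA against 22.9% in control. Reads on overlapping genes made up 0.441%, 0.443% and 0.449% against 0.435%. Reads outside genes were a smaller share in all 3 exposed libraries, at 11.9% in DMBA and 11.3% in BPA+DMBA against 13.5%, and reads given to genes made up 63.2%, 62.0% and 63.0% against 63.2%.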

How the results depend on the processing

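The alternatives that remove the length trend and leave out each library were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers that pair samples and each group is 1 library. No list median that stood apart and no named ratio at least 2-fold apart changed sign under the alternatives run for it. The larger side of the DMBA calls did change, from 909 higher and 1053 lower to 341 and 334 by DESeq2, 1260 and 1249 by the likelihood ratio test, 889 and 431 with total counts, and 537 and 386 with the length trend removed. With DMBA as the only term it changed from 1232 and 1378 to 749 and 690 without the BPA library. Of alternative values for the main counts 79 stayed within 1.5 times the main count and 28 did not. Of list medians 1198 kept their standing, apart or not, while 33 gained and 22 lost their place apart, mostly with the length trend removed or at 100 counts. The sign was compared only for medians that stood apart in the main run. Of named gene ratios 561 stayed within a distance of the main ratio set by the width of their counting interval, and 27 moved further. Where 1 library of the pair held no counts that interval is unbounded, so those ratios could not be labelled as moved. Correlations moved only without a low-count filter, to -0.0548 for BPA and 0.430 for DMBA. Total counts moved the median of all genes in DMBA against control from -0.0080 to 0.10.

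With at least 100 counts, fewer genes were left, and those at least 2-fold apart numbered 22 in BPA against control, 528 in DMBA against control, 35 in BPA+DMBA against DMBA, 267 against BPA and 3.3e2 against control (221 higher and 105 lower), with 0 shared by the BPA pairs, 209 departing from additivity and 10 shared against the common control. Without a filter more genes entered, and BPA against control gave 172. A prior count of 5 left 2 genes shared by the BPA pairs, and thinning left 0, and the cause was not tested. The stricter 4-fold threshold gave 5, 173, 7, 57 and 85 genes in the 5 pairs in the same order, 0 shared by the BPA pairs, 41 shared by the DMBA pairs, 39 departing from additivity and 2 shared against the common control.

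For BPA over both backgrounds, DESeq2 called 1 gene, the likelihood ratio test 6 and the fit without a filter 2, against 0. The fits that left out each library had BPA as the only term, which puts the DMBA difference into the error. They therefore cannot decide whether the BPA result holds. For DMBA, DESeq2 called 675, of which 669 were also among the 1962 of edgeR, a minimum of 100 counts 1164, thinning 781 and removal of the length trend 923, of which 884 were among the 1962. With DMBA as the only term all 4 libraries gave 2610, and leaving out each library gave 1049 (without control) to 2728 (without BPA+DMBA), where a lone library is assumed to vary like the others. The cause of these differences was not tested. At a minimum of 100 counts 11675 genes entered, against 13638 in the main fit. Depth limits the BPA+DMBA library most, at 15672532 counts.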

Other observations

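The DMBA difference was larger without BPA than with it for most called genes. Of the 1962 genes called for DMBA, 1270 (64.73%) had the larger ratio in DMBA against control, with a median absolute log2 ratio of 0.62 there and 0.52 in BPA+DMBA against BPA. This comparison was chosen after the data were seen and was not tested. The other grouping of the 4 libraries, control with BPA+DMBA against BPA with DMBA, gave 0 calls by edgeR and 179 genes at an unadjusted p under 0.05, where the split by BPA gave 0 and 32 and the split by DMBA 2610 and 4713. Each grouping was the only term of its fit, so the error of the split by BPA includes the DMBA difference.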
